A study of Mus musculus with 95 samples.

How the data were processed

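The deposited values were raw counts per gene for 95 libraries, as whole numbers. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, aligned to the mouse genome (GRCm38, mm10) with HISAT2 2.0.5, marked for duplicates with Picard and counted per gene with featureCounts. The strand setting and the annotation release were not given in the sources used here. Of 53465 gene entries, 3433 had no symbol and 99.8% of the IDs were found in GENCODE M21, which was used for gene positions on GRCm38.

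Every library was placed in 1 of 27 groups from its title: HSC, HPC-1 or HPC-2, at steady state or at 3, 4, 5, 6, 8, 10, 13 or 16 weeks after transplant. For 2 libraries the title read 10k where the other titles gave weeks, and both were placed at 10 weeks. For 1 HPC-2 library the title gave 3 weeks and the treatment label gave no treatment; the title was followed. The column of HPC-2 steady-state replicate 7 joined 2 description numbers in its name. The labels gave the same sort gate for all 3 populations. The labels do not say that the libraries of a group came from separate animals, so p measures the spread between these samples.

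The comparisons, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. Each population was fitted on its own, with 1 mean per group, and 3 kinds of question were asked: the mean of the 8 week groups against steady state, each week against steady state, and the slope per doubling of weeks over the transplanted libraries. HSC were tested against steady state at every week, and HPC-1 and HPC-2 at 3 and 16 weeks. HSC at steady state were set against HPC-1 and HPC-2 at steady state, and the difference in the average transplant effect between HSC and each progenitor population was tested in a fit of all libraries. Steady-state libraries are shared by all tests of a population.

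Genes were kept by the expression filter of edgeR, libraries were scaled by TMM, and each gene was tested with the edgeR quasi-likelihood F test. Adjusted p was obtained by the Benjamini-Hochberg procedure within each comparison, and genes with an adjusted p under 0.05 were called. DESeq2 and limma voom with sample weights served as alternatives. Log2 changes are those of the edgeR fit, with the standard error (SE) taken from the F statistic. Levels are counts scaled to library size (CPM), as means over the libraries of a group.

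In all, 31 gene lists were written from general knowledge of blood stem cells, cell cycle, metabolism and stress. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01, and adjusted over the lists of a comparison. For the 3 average effects the adjustment was over all 87 tests. The alternatives were camera with a correlation estimated from the data, and fry. List scores are the mean of log2(CPM + 1) over the list.

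The genes named for a comparison are the 6 with the largest rise and the 6 with the largest fall among called genes with a mean of at least 10 CPM and at least 80% of the libraries on their own side of the midpoint. That last condition was not used for slopes and interactions. Up to 4 members with the smallest p are named for each list described, as are the sort markers Slamf1, Cd48, Kit and Ly6a in the steady-state comparisons. Other genes are named where 5 or fewer were called, which is said in place.

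After the values were seen, 5 further choices were examined. Libraries with fewer than 10000 detected genes were left out (12 libraries), libraries that formed pairs with nearly the same counts were left out (12 libraries in 6 pairs), and genes with a mean under 10 CPM were left out. For the average effects, the transplanted libraries of a population were also taken as 1 group, without and with a block for every 12 description numbers. For the pairs, the 4465 pairs of libraries were compared by a chi-square of their counts per degree of freedom.

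The procedure was tested on simulated data, drawn as negative binomial counts from the means, library sizes and dispersions of the real libraries, with changes of 4-fold and 16-fold in 100 genes each. For the HSC average effect it recovered 35% of the 4-fold and 84% of the 16-fold changes with 214 false calls, 209 of them lower. The same fit recovered 10% and 28% at 3 weeks in HSC with 0 false calls. For the HPC-1 average effect it recovered 74% and 97% with 88 false calls (85 lower), for the HPC-2 average effect 23% and 62% with 175 (174 lower), and for the HSC slope 74% and 94% with 26. The HSC to HPC-1 interaction recovered 13% and 49% with 7 false calls, and HSC against HPC-1 at steady state 7% and 41% with 2. Among genes of at least 10 CPM the averages had 22, 11 and 30 false calls. Power was thus low for the single week, the interaction and the population comparison.

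Computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and the data.table package (version 1.17.8), and Python 3.11.15 with matplotlib 3.10.9 for figures.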

Results

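The libraries were made from sorted mouse bone marrow cells by SMART-Seq v4, which copies RNA from few cells, and sequenced in bulk. The labels name 3 populations of blood stem and progenitor cells, HSC, HPC-1 and HPC-2. Each was taken from untreated mice (steady state) and from mice given 900 cGy of irradiation and 8000 transplanted Lin-Sca1+Kit+ cells, at 8 times from 3 to 16 weeks later. There were 8 steady-state libraries of HSC, 8 of HPC-1 and 7 of HPC-2, and 3 libraries per population and week. Total counts per library ran from 3551908 to 8492759, with a median of 5628592. Genes detected per library ran from 3827 to 15697, with a median of 12943, and mitochondrial genes took 0.294% to 3.18% of the counts.

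Fewer than 10000 genes were detected in 12 libraries, and these fell unevenly over the groups. They were HSC steady-state replicates 1, 3 and 8, HPC-2 steady-state replicates 1, 3, 4 and 6, HSC at 13 weeks replicate 2 and at 16 weeks replicate 3, and HPC-2 at 13 weeks replicate 1 and at 16 weeks replicates 1 and 2. HPC-2 steady-state libraries had a mean of 9174 detected genes ± 3341 (SD, n = 7), against 12090 ± 2464 (n = 24) in transplanted HPC-2. In HSC the means were 11840 ± 3153 (n = 8) and 12180 ± 1873 (n = 24), and in HPC-1 13960 ± 1114 (n = 8) and 12950 ± 1574 (n = 24).

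**Figure D1:**
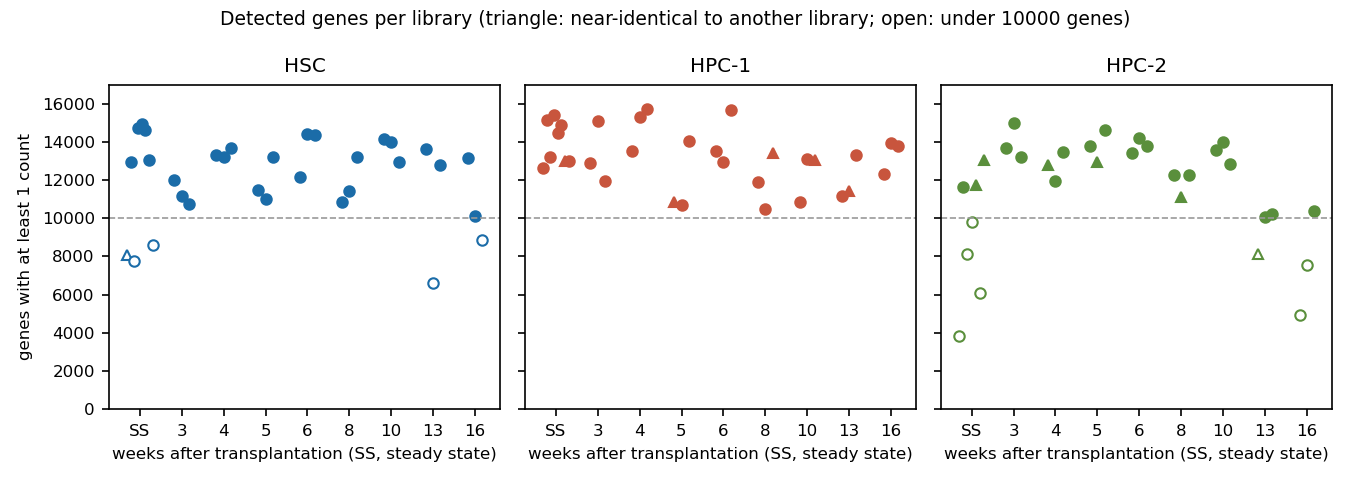
Genes with at least 1 count per library (vertical axis) at steady state and by week after transplant (horizontal axis), 1 panel per population and 1 point per library; open points mark libraries under 10000 genes and triangles mark libraries of near-identical pairs. The 4 lowest steady-state HPC-2 libraries lie between 3827 and 9809 genes.

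Among 4465 pairs of libraries, 6 pairs under different labels had nearly the same counts. Their chi-square per degree of freedom was 1.27 to 4.63, while the next smallest value was 16.3 and the median of the other pairs was 128. The pairs were HPC-2 4 weeks replicate 1 with HPC-2 5 weeks replicate 2, HPC-1 8 weeks replicate 3 with HPC-1 10 weeks replicate 3, and 4 pairs across populations. Those 4 were the steady-state replicates 7 of HPC-1 and HPC-2, HPC-1 13 weeks replicate 2 with HPC-2 steady-state replicate 5, HPC-1 5 weeks replicate 1 with HPC-2 8 weeks replicate 2, and HSC steady-state replicate 1 with HPC-2 13 weeks replicate 1. In the 3 pairs of HPC-1 with HPC-2, the library labelled HPC-2 had the profile of HPC-1. Dntt was at 447, 186 and 684 CPM in HPC-2 steady-state replicates 7 and 5 and HPC-2 8 weeks replicate 2, and at most 27.5 CPM in every other HPC-2 library, and Pf4 was at 10.3, 25.4 and 22.5 CPM. All HSC libraries at 3 weeks and replicate 1 at 4 weeks, in no pair, were nearer to the HPC-2 than the HSC mean. Their Spearman rho was 0.791 to 0.872 and 0.676 to 0.857. The HSC library paired with HPC-2 was nearer to HPC-2 too (0.682 and 0.576). In markers picked after the values were seen it had Ly6a at 37.1 CPM and no Hlf, against at least 160 and 17.2 CPM in every other HSC library, but Cd48 at 42.1 CPM, against at least 113 CPM in every HPC-2 library outside the pair. For the other 3 pairs the label could not be read from the values. No label was changed, and counts without these libraries are given for the comparisons they affected.

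**Figure D2:**
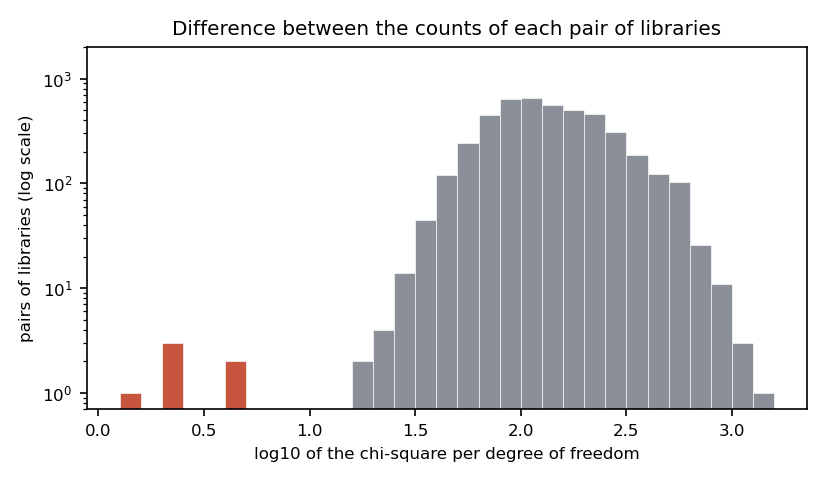
Number of library pairs (vertical axis) by log10 of the chi-square of their counts per degree of freedom (horizontal axis), over 4465 pairs. The 6 near-identical pairs, in red, lie apart from all others, the smallest of which is 16.3.

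HSC at steady state differed from HPC-1 in genes of stem cells, platelets and lymphoid progenitors. Plac8, a small cysteine-rich protein of myeloid and lymphoid progenitors (ENSMUSG00000029322, chromosome 5, 100553725 to 100572245, minus strand), was lower in HSC by a log2 change of -4.15 (SE 0.46), at a mean of 176 CPM in HSC (n = 8) against 3343 CPM in HPC-1 (n = 8; adjusted p = 1.38e-05). Dntt, which encodes the terminal transferase of developing lymphocytes, had counts in 1 HSC library and in all 8 HPC-1 libraries, at means of 0.0287 and 1022 CPM (adjusted p = 0.0023). Cd48, a marker used to sort progenitors away from stem cells, was at 16.9 CPM in HSC and 1230 CPM in HPC-1 (log2 change -6.07, SE 1.00, adjusted p = 0.0037). Pf4, a platelet chemokine gene (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383, plus strand), was higher in HSC, at 444 CPM against 19.5 CPM (log2 change 4.59, SE 0.85, adjusted p = 0.0158).

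In this comparison 15 genes were higher and 50 lower in HSC. Cavin2 and Glipr1l1 had no counts in any of the 8 HPC-1 libraries and means of 125 and 28.9 CPM in HSC (adjusted p = 0.0245 and 0.0338). Vwf, the von Willebrand factor gene (log2 change 8.31, SE 1.96, adjusted p = 0.0435), Cpne8 (7.16, SE 1.63, adjusted p = 0.0472) and Nupr1 (6.81, SE 1.62, adjusted p = 0.0476) were also higher. The genes Cox6a2, Cd244, Wfdc18, Rag2 and Il7r had no counts in HSC and means of 92.2, 53.0, 55.6, 97.7 and 44.1 CPM in HPC-1 (adjusted p = 0.0245, 0.0245, 0.0245, 0.0250 and 0.0388). Of the sort markers, Slamf1 was at 68.7 and 0.623 CPM (adjusted p = 0.17) and was not called, Kit was at 223 and 97.4 CPM, and Ly6a at 340 and 368 CPM.

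Genes of stem cell identity were higher in HSC as a list, with 22 of 24 members positive. The list had adjusted p = 2.21e-16, and adjusted p = 0.0132 with an estimated correlation. Gata2 (3.25, SE 0.65) and Pdzk1ip1 (3.42, SE 0.71) were called, both at adjusted p = 0.0245, and adjusted over the list alone 7 members were called. All 19 ageing-associated genes were positive (adjusted p = 2.71e-34, and adjusted p = 0.000165 with an estimated correlation). Of these, 2 were called over all genes and 12 over the list alone, led by Cavin2, Nupr1 and Gda. Megakaryocyte genes were higher too, 14 of 15 members being positive (adjusted p = 6.27e-23, and adjusted p = 0.000922 with an estimated correlation). Pf4, Cd9 (1.81, SE 0.37, adjusted p = 0.0245) and Vwf were called, and 11 over the list alone.

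Multipotent progenitor genes were lower in HSC, with 0 of 14 members positive (adjusted p = 6.18e-23, and adjusted p = 0.000922 with an estimated correlation). Plac8, Cd48, Nkg7 (-1.98, SE 0.41) and Ccl9 (-10.07, SE 2.08) were called over all genes, the last 2 at adjusted p = 0.0245, and 10 members over the list alone. Lymphoid priming genes were lower as well, with 0 of 18 members positive (adjusted p = 1.73e-27, and adjusted p = 0.00437 with an estimated correlation). The 3 members Dntt, Rag2 and Il7r were called over all genes, and 11 over the list alone. Dendritic cell genes had 1 of 6 members positive (adjusted p = 0.000237, and adjusted p = 0.024 with an estimated correlation). Flt3 led them (2.30 against 223 CPM, adjusted p = 0.0856), with 0 called over all genes and 3 over the list alone. Without low libraries the lymphoid and dendritic cell lists lost their calls with an estimated correlation (adjusted p = 0.0663 and 0.0808).

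Leaving out single libraries moved the number of called genes from 65 to between 7 and 121, the lowest without HPC-1 steady-state replicate 2 or 4 and the highest without HPC-2 steady-state replicate 1. The calls of Plac8, Cd48 and Dntt held in every case. Pf4 lost its call without HPC-1 steady-state replicate 2 (adjusted p = 0.051) or 4 (adjusted p = 0.0511). All 65 genes were also called without the near-identical and low libraries, where 447 were called.

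HSC at steady state differed from HPC-2 in 151 genes. Plac8 was lower in HSC by a log2 change of -3.15 (SE 0.44), at 176 CPM (n = 8) against 1590 CPM (n = 7; adjusted p = 0.00142). Il4, the interleukin 4 gene, and Fam110c had no counts in any HPC-2 library and means of 90.0 and 85.8 CPM in HSC (both at adjusted p = 0.0136). The replication gene Mcm4 was lower in HSC, at 75.0 against 340 CPM (log2 change -2.19, SE 0.52, adjusted p = 0.0403). So was the thymidylate synthase gene Tyms, at 209 against 521 CPM (-1.33, SE 0.32, adjusted p = 0.0435).

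Here 122 genes were higher and 29 lower in HSC. Cpne8, Fgd5 and Glipr1l1 had no counts in HPC-2 and means of 36.6, 44.2 and 28.9 CPM in HSC (adjusted p = 0.0251, 0.0322 and 0.0362). Nkx2-3 was at 26.2 and 0.0526 CPM (adjusted p = 0.0322). Nkg7 (-2.24, SE 0.42, adjusted p = 0.0206), Cd48 (-4.97, SE 0.96, adjusted p = 0.0251) and Lgals1 (-2.07, SE 0.41, adjusted p = 0.0322) were lower in HSC. Of the other sort markers, Slamf1 was at 68.7 and 25.6 CPM (adjusted p = 0.89), Kit at 223 and 64.3 CPM (0.454) and Ly6a at 340 and 330 CPM (0.994), none of them called.

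DNA replication genes were lower in HSC than in HPC-2, 1 of 27 members being positive (adjusted p = 4.29e-10, but adjusted p = 0.0923 with an estimated correlation). Mcm4, Tyms and Mcm7 (-1.84, SE 0.47, adjusted p = 0.0478) were called over all genes and 5 members over the list alone. Ribosome biogenesis genes had 5 of 26 members positive (adjusted p = 3.11e-07, but adjusted p = 0.215 with an estimated correlation). Nop56 was called (-1.16, SE 0.29, adjusted p = 0.0467), and 2 over the list alone. HSC identity genes had 22 of 24 members positive (adjusted p = 2.02e-07, but adjusted p = 0.234 with an estimated correlation). Fgd5 was called, and 4 over the list alone. Ageing-associated genes had 17 of 19 positive (adjusted p = 5.64e-09, but adjusted p = 0.0923 with an estimated correlation). Ghr, Clu, Jam2 and Ramp2 were called (adjusted p = 0.0342, 0.0389, 0.0389 and 0.0478), and 5 over the list alone. Without low libraries 3 of these lists were called with an estimated correlation: HSC identity (adjusted p = 2.59e-05), DNA replication (0.00464) and ageing-associated genes (0.000548). That left 3 HPC-2 libraries, 2 of them with the HPC-1 profile. Without near-identical libraries none was (adjusted p = 0.126, 0.126 and 0.137).

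The number of genes called between HSC and HPC-2 ran from 4 without HSC steady-state replicate 6 to 590 without HPC-2 steady-state replicate 7, which is 1 of a near-identical pair with HPC-1. Without near-identical libraries 1574 genes were called and without low libraries 69, with 138 and 32 of the 151 among them. With a block by replicate or description number few were called. Plac8, Il4, Fam110c and Cpne8 kept their calls whichever library was left out. Cd48 and Nkg7 lost them without HSC steady-state replicate 4 (adjusted p = 0.0519) or 6 (adjusted p = 0.0568).

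On average over the 8 weeks, transplanted HSC had more Plac8 than HSC at steady state. Its level rose from 176 to 720 CPM (log2 change 1.88, SE 0.32, n = 8 and 24, adjusted p = 0.0159), and the call held when any single library was left out. The cytochrome oxidase gene Cox5a rose from 231 to 357 CPM (0.60, SE 0.17, adjusted p = 0.0321), and Tyms from 209 to 387 CPM (0.85, SE 0.23, adjusted p = 0.0291). The stem cell gene Fgd5 fell from 44.2 to 5.09 CPM (-4.27, SE 1.04, adjusted p = 0.0215) and Txnip, an inhibitor of thioredoxin, fell from 304 to 146 CPM (-1.19, SE 0.29, adjusted p = 0.0221). Hmgn2 rose (0.43, SE 0.13, adjusted p = 0.0492), but this gene has many processed copies in the genome that share its reads, so its value is uncertain.

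In all, 14 genes were higher and 741 lower. This average is a mean of log2 levels per week, so a gene with no count in some weeks could receive a large fall, and in simulated data 209 of the 214 false calls of this test were lower. Of the 755 called genes 67 had a mean of at least 10 CPM, and the median over called genes was 1.61 CPM. With all transplanted libraries as 1 group, edgeR called 0 genes. In the grouping by week DESeq2 called 565 and voom 327. Among genes with a mean of at least 10 CPM, 2 were called. The median log2 change of all genes was -0.393 with TMM and -0.549 with RLE scaling, which called 7 genes higher and 915 lower. Without near-identical libraries 745 genes were called, 675 of them among the 755. Counts of called genes ran from 442 without steady-state replicate 5 to 1312 without 16 weeks replicate 1, with 10 of 32 libraries moving them by more than 1.5-fold.

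HSC identity genes had 6 of 25 members positive on average, with 4 called, among them Fgd5, Txnip and Robo4 (the last at adjusted p = 0.0248), and 5 over the list alone. The list itself was not called (adjusted p = 0.576), but without the low libraries it was (adjusted p = 1.47e-07, and adjusted p = 0.00796 with an estimated correlation). Its direction turned with fry (adjusted p = 0.992) and without steady-state replicate 8 (0.949). Ageing-associated genes had 7 of 24 positive (adjusted p = 0.0966), with Wwtr1, Ptprk, Neo1 and Ramp2 called (adjusted p = 0.0159, 0.0162, 0.0251 and 0.0252) and 5 over the list alone. Without the low libraries that list had adjusted p = 0.00212, and adjusted p = 0.0297 with an estimated correlation. Without HSC steady-state replicate 1 alone, the first list reached adjusted p = 5.88e-06 and the second 0.00072. Txnip lost its call without steady-state replicate 4 (adjusted p = 0.0542) and Robo4 without 6 (adjusted p = 0.0583).

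Oxidative phosphorylation genes were higher on average in transplanted HSC, with 34 of 36 members positive (adjusted p = 2.05e-06, but adjusted p = 0.558 with an estimated correlation). Cox5a was the 1 member called, over all genes and over the list alone. Cox5a lost its call without steady-state replicate 4, 5, 7 or 8 (adjusted p = 0.0679, 0.0551, 0.0516 and 0.0551) and with RLE scaling (0.0964). DNA replication genes had 17 of 27 positive (adjusted p = 0.0277, but adjusted p = 0.686 with an estimated correlation). Their median log2 change was 0.24 but their mean was -0.10. Tyms was called, and over the list alone 2 were higher and 1 lower. The list lost its call without any of 8 libraries, up to adjusted p = 0.19 without steady-state replicate 8. Tyms lost its call without steady-state replicate 4, 5 or 7 (adjusted p = 0.0516, 0.0592 and 0.0614). Imprinted genes had 1 of 9 positive (adjusted p = 0.00251, but adjusted p = 0.558 with an estimated correlation). Meg3, H19 and Dlk1 were called, and 5 over the list alone. Meg3 had counts in 1 of 24 transplanted and 5 of 8 steady-state libraries, at means of 0.00701 and 2.53 CPM (adjusted p = 0.0159). That list lost its call without steady-state replicate 5 (adjusted p = 0.551), 6 (0.094) or 7 (0.12).

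Immediate early genes, which respond within minutes to stress and signals, were lower on average, 1 of 21 members being positive (adjusted p = 0.032, but adjusted p = 0.686 with an estimated correlation). Of these, 4 were called over all genes and 10 over the list alone. Nr4a1 was at 53.7 CPM after transplant and 79.4 CPM at steady state (-3.79, SE 0.79, adjusted p = 0.0159), Klf4 at 45.8 and 54.3 CPM (-3.14, SE 0.75, adjusted p = 0.0215). Egr1 was at 211 and 483 CPM (-1.48, SE 0.36, adjusted p = 0.0215) and Egr3 at 2.38 and 3.32 CPM (-4.51, SE 1.18, adjusted p = 0.0319). The list lost its call without any of 21 libraries (up to adjusted p = 0.413 without steady-state replicate 3). Nr4a1 and Egr1 lost theirs without steady-state replicate 5 (0.0915 and 0.0581), and Klf4 without 3 (0.0918). Weeks without a count could enlarge these falls. The mean score of the list was 5.43 (SD 1.32) at steady state and 5.17 (SD 1.29) after transplant. Monocyte and macrophage genes had 1 of 10 positive (adjusted p = 0.0222, but adjusted p = 0.606 with an estimated correlation). Led by Cd14, Mrc1, Ly6c2 and C1qb, 5 were called over all genes and 7 over the list alone. The list lost its call without any of 7 libraries (up to adjusted p = 0.301 without steady-state replicate 5).

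**Figure D3:**
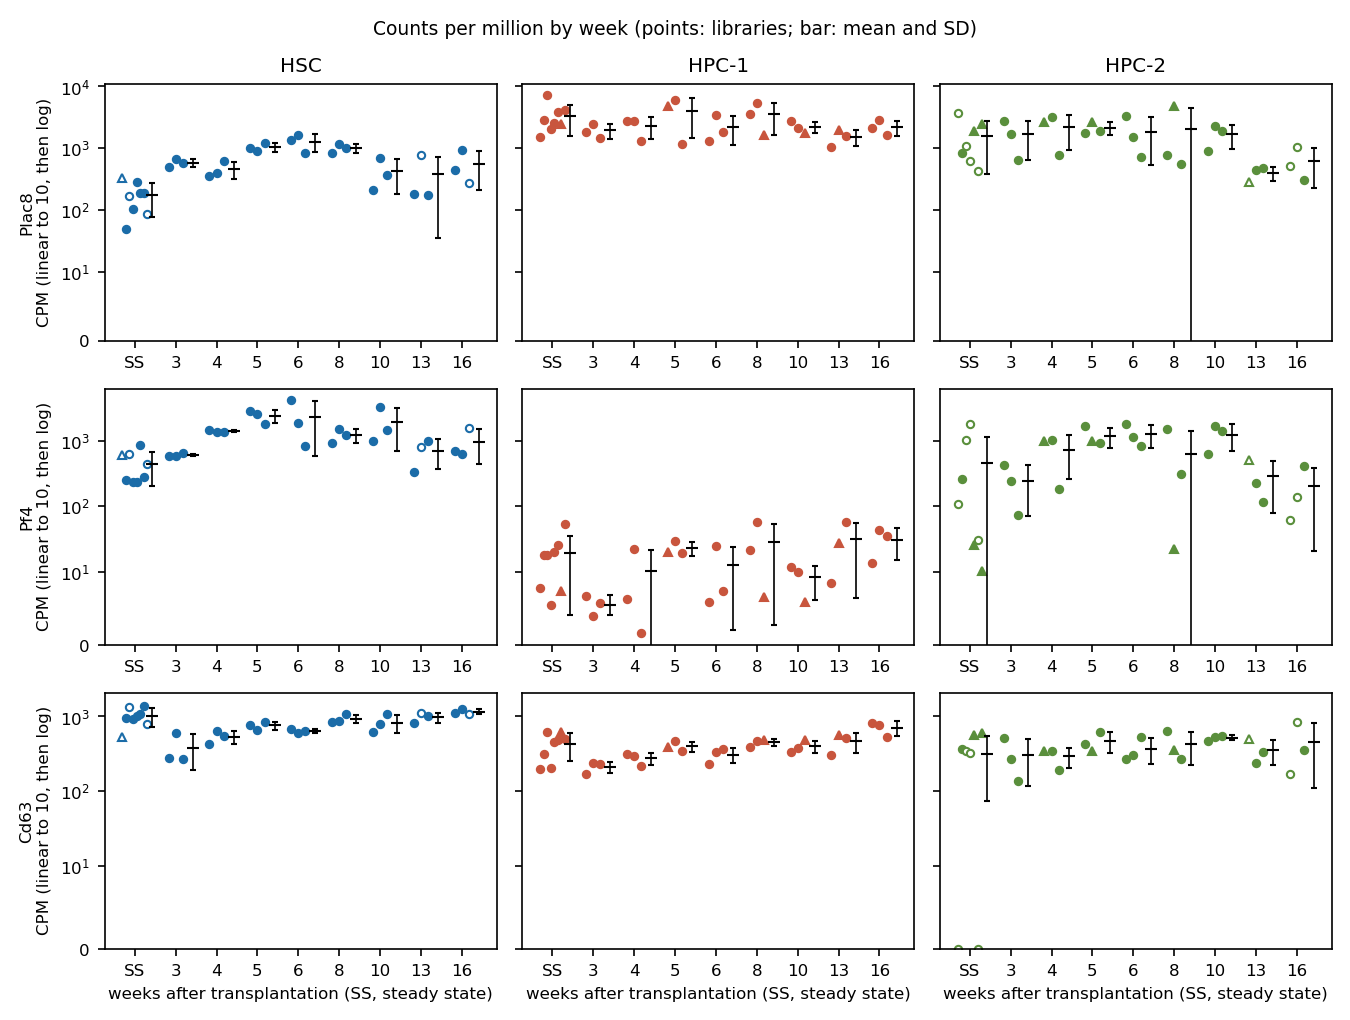
Plac8, Pf4 and Cd63 in CPM (vertical axis, linear to 10 and logarithmic above) at steady state and by week after transplant (horizontal axis), in HSC, HPC-1 and HPC-2; points are libraries, with group mean and SD. Plac8 in HSC rises from a mean of 176 CPM to 1291 CPM at 6 weeks.

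At 3 weeks cell division genes were higher in HSC as a list. DNA replication genes had 24 of 27 members positive (adjusted p = 4.61e-10, but adjusted p = 0.284 with an estimated correlation), with 0 members called, also over the list alone. Slbp was at 661 CPM (n = 3) against 354 CPM at steady state (0.94, SE 0.31, adjusted p = 0.283), Mcm7 at 311 and 116 CPM (1.47, SE 0.49, adjusted p = 0.293). Mcm4 was at 350 and 75.0 CPM (2.26, SE 0.81, adjusted p = 0.33) and Mcm2 at 275 and 79.0 CPM (1.83, SE 0.66, adjusted p = 0.331). Without low libraries the list held with an estimated correlation (adjusted p = 0.00861), and Mcm7 (1.73, adjusted p = 0.0418) and Mcm2 (2.44, adjusted p = 0.0339) were among 4 members called.

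Interferon response genes were higher at 3 weeks in HSC, with 22 of 32 members positive (adjusted p = 0.000355, but adjusted p = 0.491 with an estimated correlation) and 0 called either way. Of the members with the smallest p, Mx1 had 0 and 3.09 CPM, Igtp 405 and 79.5 CPM (adjusted p = 0.395) and Stat2 61.9 and 7.11 CPM (adjusted p = 0.403). Immediate early genes were lower, with 1 of 21 positive (adjusted p = 0.00141, but adjusted p = 0.552 with an estimated correlation). Of them 7 were called over the list alone, and 0 over all genes. Klf4 and Nr4a1 had no counts at 3 weeks, against 54.3 and 79.4 CPM at steady state (adjusted p = 0.176 and 0.182). That list lost its call without 3 weeks replicate 1 (adjusted p = 0.0627). Over the 3 populations, the immediate early score of the steady-state libraries with the same 12 description numbers was also low. It lay at -2.03 from the steady-state mean, and the transplanted libraries at -1.12 from theirs. Ribosomal protein genes, whose reads are shared with many pseudogenes and are therefore uncertain, had 0 of 33 positive (adjusted p = 1.40e-07, but adjusted p = 0.561 with an estimated correlation). Of them 29 were called over the list alone and 0 over all genes, Rpl10a, Rpl7 and Rps18 all having adjusted p = 0.221. The edgeR fit called 0 single genes at 3 weeks, with 1760 at an unadjusted p under 0.05, while DESeq2 called 710 and voom 758. Without steady-state replicate 1 it called 95, and without low libraries 148, among them Rps18 (adjusted p = 0.0423) and Klf4 (adjusted p = 0.0087).

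At 4 weeks Rap1b, which encodes a small GTPase of cell adhesion (ENSMUSG00000052681, chromosome 10, 117813871 to 117846035, minus strand), rose in HSC from 937 to 2585 CPM (log2 change 1.51, SE 0.25, n = 8 and 3, adjusted p = 0.0255). It was the 1 gene called, and lost its call without any of 9 libraries (up to adjusted p = 0.793 without 4 weeks replicate 1) and with only the 2 compared groups (0.159). Mitosis genes were higher, 26 of 27 members being positive (adjusted p = 3.79e-12, but adjusted p = 0.294 with an estimated correlation; without low libraries the latter was 0.0397), with 0 called either way. Ccnb2 was at 620 against 235 CPM, Cdk1 at 517 against 257 CPM and Birc5 at 560 against 259 CPM (each at adjusted p = 0.978). Megakaryocyte genes had 12 of 16 positive (adjusted p = 0.000522, but adjusted p = 0.331 with an estimated correlation). Pf4 (1.69, SE 0.40, adjusted p = 0.599) and Cd9 (0.83, SE 0.24, adjusted p = 0.978) came first, with 2 called over the list alone and 0 over all genes. Imprinted genes had 0 of 9 positive (adjusted p = 0.000254, but adjusted p = 0.294 with an estimated correlation; 0.119 without steady-state replicate 5). None was called either way, and Meg3 and Igf2r had no counts at 4 weeks.

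At 5 weeks Pf4 and Plac8 were the 2 genes called in HSC. Pf4 rose from 444 to 2401 CPM (log2 change 2.40, SE 0.40, n = 8 and 3) and Plac8 from 176 to 1052 CPM (2.54, SE 0.43), both at adjusted p = 0.0176. Both lost the call without steady-state replicate 4 (adjusted p = 0.0561), without 5 weeks replicate 1 (0.095 for Pf4 and 0.0763 for Plac8) and without replicate 2 (0.0641), and Plac8 also without replicate 3 (0.203). With RLE scaling (0.178 and 0.221) and with only the 2 compared groups (0.253 and 0.43) neither was called. Oxidative phosphorylation genes had 30 of 36 members positive (adjusted p = 8.73e-11, but adjusted p = 0.303 with an estimated correlation). Cycs (716 against 309 CPM) and Cox5a (419 against 231 CPM) came first (adjusted p = 0.621 each), with 1 called over the list alone and 0 over all genes. Immediate early genes were higher here, with 13 of 21 positive (adjusted p = 1.52e-05, but adjusted p = 0.616 with an estimated correlation) and 0 called either way. Fosl2 (43.8 against 7.11 CPM, adjusted p = 0.621) came first. Steady-state libraries with the same 12 description numbers were high as well (1.79 from their mean, and 1.58 for transplanted libraries).

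At 6 weeks 3 genes rose in HSC. Plac8 rose 7.38-fold, from 176 to 1291 CPM (log2 change 2.88, SE 0.43, n = 8 and 3, adjusted p = 0.00415). Rap1b rose from 937 to 2544 CPM (1.46, SE 0.25, adjusted p = 0.0153), and Pf4, named after the values were seen, from 444 to 2289 CPM (2.38, SE 0.40, adjusted p = 0.0141). The last 2 were lost without 6 weeks replicate 1 (adjusted p = 1), and Pf4 with voom (0.0891). All 3 were lost with RLE scaling (0.119, 0.13 and 0.13) and with only the 2 compared groups in the fit (0.2, 0.372 and 0.372). Immediate early genes were lower, with 1 of 21 members positive (adjusted p = 2.52e-11, but adjusted p = 0.168 with an estimated correlation). Of them 11 were called over the list alone, and 0 over all genes. Fos was at 231 against 1129 CPM (-2.28, SE 0.46, adjusted p = 0.124) and Egr1 at 45.2 against 483 CPM (-3.39, SE 0.79, adjusted p = 0.377). Here the steady-state libraries with the same description numbers lay at -0.36 from their mean and the transplanted ones at -1.32. B cell genes had 5 of 5 positive (adjusted p = 6.52e-05, but adjusted p = 0.168 with an estimated correlation; 0.132 without 6 weeks replicate 3), with 3 called over the list alone and 0 over all genes. Cd79a, Igll1 and Vpreb3 were seen in 2 of 3 libraries, at means of 9.91, 12.7 and 6.90 CPM, and in no steady-state library.

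From 8 weeks on the edgeR fit called 0 genes in HSC at each time. At 8 weeks 1080 genes had an unadjusted p under 0.05, and DESeq2 called 640 and voom 313. At 10 weeks the values were 388, 119 and 84, at 13 weeks 705, 273 and 21, and at 16 weeks 1450, 937 and 53. Without 16 weeks replicate 1 the fit called 59 genes at 16 weeks. Ribosomal protein genes were higher at 8 weeks, with 32 of 33 members positive (adjusted p = 1.44e-20, but adjusted p = 0.494 with an estimated correlation). At 16 weeks 32 were again positive (adjusted p = 8.05e-32, but adjusted p = 0.286 with an estimated correlation), and 0 were called at either time. At 10 weeks megakaryocyte genes were higher, with 14 of 16 positive (adjusted p = 0.00016, but adjusted p = 0.219 with an estimated correlation). Pf4 was at 1915 against 444 CPM (2.11, SE 0.40, adjusted p = 0.183) and Cd9 at 1167 against 524 CPM (1.16, SE 0.24, adjusted p = 0.189). Of them 2 were called over the list alone, and 0 over all genes. Monocyte and macrophage genes had 0 of 10 positive at 10 weeks (adjusted p = 5.56e-08, but adjusted p = 0.0985 with an estimated correlation; without low libraries 0.00649). At 13 weeks immediate early genes had 1 of 21 positive (adjusted p = 0.0114, but adjusted p = 0.886 with an estimated correlation). Klf2 was at 2.18 against 127 CPM and Egr1 at 94.4 against 483 CPM (adjusted p = 0.885 each), with 2 called over the list alone. The list lost its call without steady-state replicate 3 (0.0824), 13 weeks replicate 1 (0.0874) or 3 (0.0984), and steady-state libraries with the same description numbers were low too (-1.58, and -1.05 for transplanted libraries).

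Over the 8 weeks after transplant, Cd63, which encodes a tetraspanin of late endosomes, rose in HSC. Its slope was a log2 change of 0.53 per doubling of weeks (SE 0.09, n = 24, adjusted p = 0.0225), with 385 CPM at 3 weeks and 1158 CPM at 16 weeks. The chaperone gene Hspa8 fell, from 3877 to 1114 CPM (-0.57, SE 0.12, adjusted p = 0.0293). Malat1, a nuclear long RNA, rose from 202 to 996 CPM (0.69, SE 0.15, adjusted p = 0.0418), and Itm2a from 69.4 to 356 CPM (0.90, SE 0.20, adjusted p = 0.0489). Malat1 and Itm2a lost their calls without 16 weeks replicate 2 (adjusted p = 0.0648 and 0.0687), as did Hspa8 with weeks on a linear scale (0.114). In all, 21 genes rose and 10 fell, of which 4 had a mean of at least 10 CPM. Leaving out any single library of the 24 raised the count, to between 86 and 155, since a group of 2 loosens the expression filter.

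DNA replication genes fell over the weeks in HSC, with 1 of 27 members positive (adjusted p = 1.13e-06, but adjusted p = 0.384 with an estimated correlation). Of them 2 were called over the list alone, and 0 over all genes. Mcm2 went from 275 to 74.3 CPM (-0.65, SE 0.19, adjusted p = 0.171). Mitosis genes had 0 of 27 positive (adjusted p = 8.00e-09, but adjusted p = 0.4 with an estimated correlation). First came Bub1b (84.2 to 3.76 CPM, adjusted p = 0.244), with 0 called either way. Genes of the unfolded protein response had 2 of 17 positive (adjusted p = 0.00143, but adjusted p = 0.384 with an estimated correlation). Over the list alone 6 were lower, among them Hsp90b1 (824 to 269 CPM, adjusted p = 0.146). The 1 member called over all genes, Trib3, had the opposite sign and counts in 1 of 3 libraries at 16 weeks (0.417 CPM, adjusted p = 0.0262). Ribosomal protein genes had 33 of 33 positive (adjusted p = 9.43e-15, but adjusted p = 0.403 with an estimated correlation). Of them 12 were called over the list alone, and 0 over all genes.

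**Figure D4:**
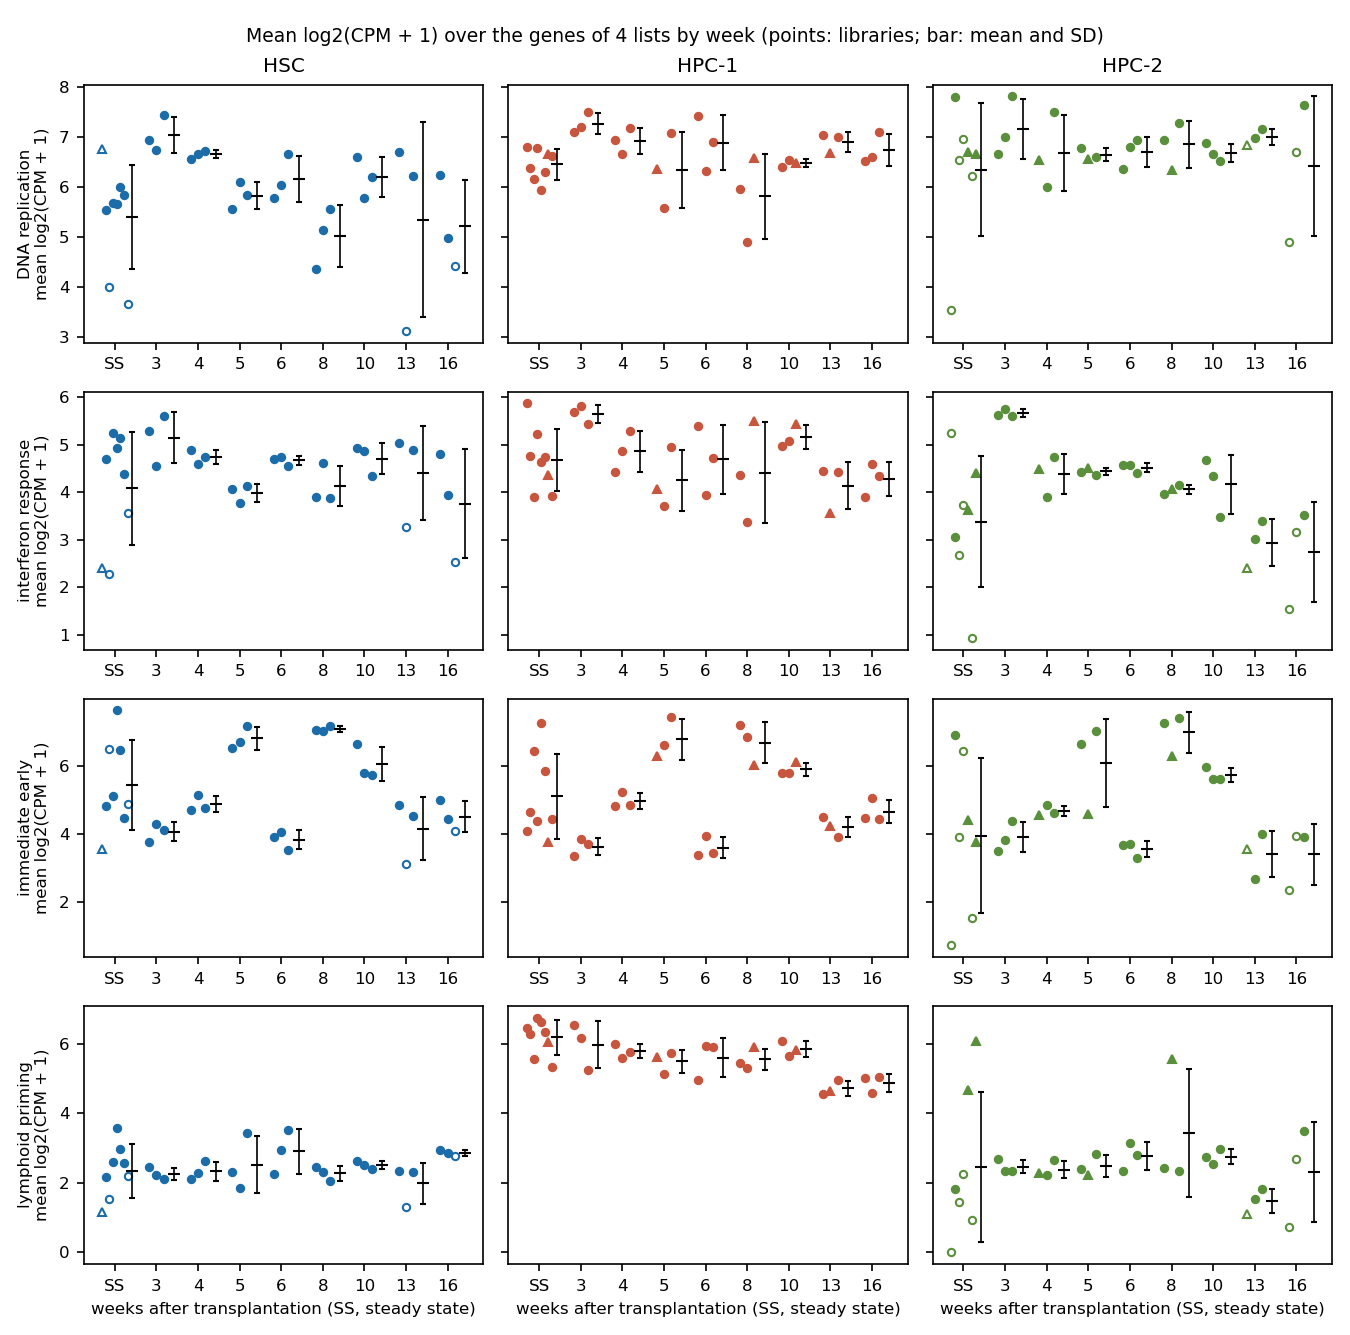
Mean log2(CPM + 1) of 4 gene lists (vertical axis) in HSC, HPC-1 and HPC-2. The horizontal axis gives steady state and the weeks after transplant. Points are libraries, with group mean and SD. Immediate early genes move together in the 3 populations, from 4.06 at 3 weeks to 7.08 at 8 weeks in HSC.

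Transplanted HPC-1 differed on average from HPC-1 at steady state in 190 genes. Selp, the P-selectin gene (ENSMUSG00000026580, chromosome 1, 164115264 to 164150026, plus strand), rose 6.41-fold, from 6.71 to 46.1 CPM (log2 change 2.68, SE 0.59, n = 8 and 24, adjusted p = 0.0265). Ctnnb1, which encodes beta-catenin (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507, plus strand), rose 2.18-fold, from 58.2 to 129 CPM (1.12, SE 0.25, adjusted p = 0.0265). Serpinf1 fell from 159 to 22.4 CPM (-3.04, SE 0.59, adjusted p = 0.0202) and Pkib from 92.6 to 47.3 CPM (-1.13, SE 0.25, adjusted p = 0.0265). The calls of Selp, Ctnnb1 and Serpinf1 held in each omission of a single library, and Pkib was lost without steady-state replicate 6 (adjusted p = 0.0535) or 7 (adjusted p = 0.053).

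In all, 5 genes were higher and 185 lower in transplanted HPC-1. The other 3 higher genes, named after the values were seen, were Tjp1 (9.95 CPM against no counts, adjusted p = 0.0257), Slfn2 (10.4 against 0.0292 CPM, adjusted p = 0.0239) and Muc13 (177 against 87.2 CPM, adjusted p = 0.0487). Tjp1 was lost without 5 weeks replicate 3, Slfn2 without 16 weeks replicate 3 (adjusted p = 1 each) and Muc13 without any of 11 libraries (up to adjusted p = 0.0953). Of the 190 called genes, 20 had a mean of at least 10 CPM, 77 were also called without near-identical libraries, and with all transplanted libraries as 1 group 2 genes were called. The count ran from 93 without steady-state replicate 6 to 432 without 5 weeks replicate 3.

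Lymphoid priming genes were lower on average in transplanted HPC-1, with 2 of 19 members positive (adjusted p = 4.41e-06, but adjusted p = 0.247 with an estimated correlation). Il12a fell from 903 to 492 CPM (-0.99, SE 0.24, adjusted p = 0.0319) as the 1 member called over all genes. Of them 7 were called over the list alone, with Rag1 (2.95 to 0.616 CPM, adjusted p = 0.0519), Ighm (1018 to 610 CPM, adjusted p = 0.059) and Ly6d (110 to 38.2 CPM, adjusted p = 0.0613) next. Dendritic cell genes had 1 of 8 positive (adjusted p = 0.0109, but adjusted p = 0.247 with an estimated correlation). Ccr9 was called (22.2 to 5.88 CPM, -4.10, SE 0.98, adjusted p = 0.0328), and 4 over the list alone. Il12a was lost without steady-state replicate 2, 5, 6, 7 or 8 (adjusted p = 0.0514 to 0.0595) and Ccr9 without 4, 5 or 6 (0.0511, 0.0993 and 0.0562). DNA replication genes had 20 of 27 positive (adjusted p = 0.00273, but adjusted p = 0.606 with an estimated correlation), with Rrm1 (adjusted p = 0.257) and Mcm3 (adjusted p = 0.27) first and 0 called either way.

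At 3 weeks an interferon-induced gene rose and a chemokine gene fell in HPC-1. Serpina3g (ENSMUSG00000041481, chromosome 12, 104236245 to 104241939, plus strand) rose from 230 to 963 CPM (log2 change 2.08, SE 0.33, n = 8 and 3, adjusted p = 0.0109), although its close paralogs share reads, so that the value is uncertain. Slfn2, named after the values were seen, rose from 0.0292 to 34.5 CPM (adjusted p = 0.017). Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355, minus strand) fell from 630 to 27.9 CPM (-4.48, SE 0.76, adjusted p = 0.0153) and Tceal8 from 157 to 38.6 CPM (-2.01, SE 0.38, adjusted p = 0.0445). These were the 4 genes called. Serpina3g was lost without 3 weeks replicate 3 (adjusted p = 0.12), Ccl3 without 3 weeks replicate 1 (0.207) or 3 (0.263) and with only the 2 compared groups (0.0568), Tceal8 with RLE scaling (0.0548). Slfn2 was lost without any of 8 libraries (up to 0.112 without steady-state replicate 2) and Tceal8 without any of 25 (up to 0.448 without 3 weeks replicate 3).

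Interferon response genes were higher in HPC-1 at 3 weeks, 25 of 32 members being positive (adjusted p = 1.26e-05, but adjusted p = 0.241 with an estimated correlation). Iigp1 was at 259 against 47.5 CPM (2.46, SE 0.69) and Igtp at 271 against 77.7 CPM (1.81, SE 0.51), each at adjusted p = 0.239, with 2 called over the list alone and 0 over all genes. DNA replication genes had 20 of 27 positive (adjusted p = 2.69e-05, but adjusted p = 0.241 with an estimated correlation). Mcm5 was at 204 against 63.3 CPM (adjusted p = 0.239) and Mcm6 at 1000 against 330 CPM (adjusted p = 0.247), with 6 called over the list alone and 0 over all genes. Glycolysis genes had 15 of 19 positive (adjusted p = 1.64e-05, but adjusted p = 0.241 with an estimated correlation). Ldhb had the opposite sign, at 28.7 against 114 CPM (adjusted p = 0.236), and Ldha was at 1547 against 939 CPM (adjusted p = 0.242). Over the list alone 5 were higher and 1 lower. Immediate early genes had 0 of 20 positive (adjusted p = 4.57e-05, but adjusted p = 0.47 with an estimated correlation). Of them 9 were called over the list alone, and 0 over all genes, with Fos at 158 against 856 CPM (-2.42, SE 0.61, adjusted p = 0.215). The steady-state libraries with the same description numbers were low here too, as given for HSC.

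At 16 weeks lymphoid priming genes were lower in HPC-1, and the list held with an estimated correlation. Of 19 members 2 were positive (adjusted p = 3.79e-11, and adjusted p = 0.0103 with an estimated correlation), 6 were called over the list alone and 0 over all genes. Il12a was at 289 CPM (n = 3) against 903 CPM at steady state (-1.64, SE 0.45), Dntt at 251 against 1022 CPM (-2.02, SE 0.59). Ighm was at 416 against 1018 CPM (-1.29, SE 0.39) and Cnn3 at 33.8 against 187 CPM (-2.46, SE 0.79), each at adjusted p = 1. Without near-identical libraries the list had adjusted p = 0.0722 with an estimated correlation. Genes of NF-kB signalling had 4 of 21 positive (adjusted p = 0.000705, but adjusted p = 0.163 with an estimated correlation; 0.0549 without 16 weeks replicate 3). Tnfaip3 was at 1.23 against 25.3 CPM and Ccl3 at 155 against 630 CPM (adjusted p = 1 each), with 2 called over the list alone. The edgeR fit called 0 single genes, with 495 at an unadjusted p under 0.05, and DESeq2 called 65 and voom 6.

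Over the weeks after transplant Gng11, a G protein subunit gene, and Cd63 rose in HPC-1. Gng11 went from 15.1 CPM at 3 weeks to 95.9 CPM at 16 weeks (log2 change 1.12 per doubling of weeks, SE 0.16, n = 24, adjusted p = 0.00196) and Cd63 from 211 to 709 CPM (0.56, SE 0.09, adjusted p = 0.00504). The annexin gene Anxa1 rose from 282 to 828 CPM (0.54, SE 0.11, adjusted p = 0.0338), Tceal8 from 38.6 to 165 CPM (0.69, SE 0.15, adjusted p = 0.0392) and Otos from 21.4 to 151 CPM (0.83, SE 0.18, adjusted p = 0.0498). Akr1c13, whose close paralogs make its value uncertain, rose from 81.0 to 266 CPM (0.61, SE 0.12, adjusted p = 0.0338). The mast cell protease gene Mcpt4 fell (adjusted p = 0.00556), with counts in 9 of 24 transplanted libraries. In all, 11 genes rose and 16 fell. Tceal8 was lost without 3 weeks replicate 1 (adjusted p = 0.0575) or 16 weeks replicate 1 (0.0808), and Otos without any of 8 libraries (up to 0.0973 without 16 weeks replicate 2). Each omission raised the count, to between 50 and 86 genes.

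Mast cell and basophil genes fell over the weeks in HPC-1, with 0 of 10 members positive (adjusted p = 1.62e-05, but adjusted p = 0.0926 with an estimated correlation). Cd200r3 was called (adjusted p = 0.034), and 7 over the list alone. Tpsb2 went from 72.6 to 1.07 CPM (-3.27, SE 0.78, adjusted p = 0.0931). Lymphoid priming genes fell as well, with 3 of 19 positive (adjusted p = 1.62e-05, but adjusted p = 0.0926 with an estimated correlation). Over all genes 1 was called, and over the list alone 4, with Dntt going from 1182 to 251 CPM (-0.76, SE 0.22, adjusted p = 0.243). Interferon response genes had 6 of 32 positive (adjusted p = 5.05e-05, but adjusted p = 0.184 with an estimated correlation). Of them 1 was called over the list alone, and 0 over all genes, with Igtp going from 271 to 36.7 CPM (-0.91, SE 0.23, adjusted p = 0.127).

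Transplanted HPC-2 could be compared on average with 7 steady-state libraries, of which 4 had few detected genes and 2 were near-identical to HPC-1 libraries. The edgeR fit called 9 genes higher and 146 lower, none of which met the conditions for being named, and 1 of the 155 was still called without both kinds of library. Voom called 4 genes and DESeq2 1135. Leaving out single libraries gave from 0 to 304 genes, the most without 16 weeks replicate 3, and 26 of 31 libraries moved the count by more than 1.5-fold. DNA replication genes were lower, with 8 of 27 members positive (adjusted p = 0.00958, but adjusted p = 0.606 with an estimated correlation; 0.11 without steady-state replicate 6) and 0 called either way. Their mean score ran the other way, at 6.35 at steady state and 6.77 after transplant, with steady-state replicate 1 apart at 3.54. Mcm7 was at 223 against 408 CPM (-1.02, SE 0.40, adjusted p = 0.197) and Mcm6 at 576 against 1017 CPM (-0.92, SE 0.39, adjusted p = 0.272). Ribosome biogenesis genes had 7 of 26 positive (adjusted p = 0.0037, but adjusted p = 0.606 with an estimated correlation). First came Fbl (70.8 against 177 CPM, adjusted p = 0.154) and Myc (326 against 599 CPM, adjusted p = 0.161), with 0 called either way and mean scores again the other way, at 6.20 and 6.47.

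At 3 weeks interferon response genes were higher in HPC-2. Of 32 members 23 were positive (adjusted p = 1.33e-05, but adjusted p = 0.708 with an estimated correlation; without low libraries the latter was 0.00354, with 3 steady-state libraries left, 2 of them with the HPC-1 profile). Of them 2 were called over the list alone, and 0 over all genes. Oasl1 had 9.22 CPM in 3 of 3 libraries and Mx2 7.23 CPM in 2 of 3, and both had no counts at steady state (adjusted p = 0.198 each). Immediate early genes had 3 of 20 positive (adjusted p = 0.00101, but adjusted p = 0.708 with an estimated correlation), with 0 called either way. The edgeR fit called 0 genes, with 1030 at an unadjusted p under 0.05, and DESeq2 called 302 and voom 379. Without steady-state replicate 2 it called 17.

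At 16 weeks Hdlbp, which encodes an RNA-binding protein (ENSMUSG00000034088, chromosome 1, 93405940 to 93478815, minus strand), had no counts in 3 HPC-2 libraries and 63.0 CPM in 7 of 7 steady-state libraries (adjusted p = 0.0018). Oxa1l, Vcpip1, Sdhaf3, Exoc5 and Tbc1d2b also had no counts at 16 weeks, against 54.4, 43.0, 54.1, 103 and 53.3 CPM (all at adjusted p = 0.0464). Each was lost without 23 or 24 of 31 libraries, up to adjusted p = 0.171 without 16 weeks replicate 1. The seventh lower gene was Pqlc3, named after the values were seen (59.7 CPM at steady state, adjusted p = 0.0464). With only the 2 compared groups all 7 were lost (adjusted p = 0.607 each), and with RLE scaling all but Hdlbp. Of the 3 libraries at 16 weeks 2 had few detected genes, and the count ran from 1 to 450 genes, the latter without 16 weeks replicate 3. Without near-identical libraries 5 genes were called, 2 of them among the 7. Mitosis genes had 27 of 27 members positive (adjusted p = 7.01e-14, but adjusted p = 0.352 with an estimated correlation), with 0 called either way. Prc1 was at 351 against 60.5 CPM (2.55, SE 1.12, adjusted p = 0.244).

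Over the weeks interferon-induced genes fell in HPC-2. Tgtp2, a GTPase gene whose near-identical neighbour makes its value uncertain, went from 445 CPM at 3 weeks to 78.2 CPM at 16 weeks (log2 change -1.12 per doubling of weeks, SE 0.22, n = 24, adjusted p = 0.0208). Ube2l6 fell from 580 to 233 CPM (-0.58, SE 0.14, adjusted p = 0.0486) and the immunoproteasome gene Psmb9 from 499 to 238 CPM (-0.44, SE 0.11, adjusted p = 0.0496). The interferon response list had 5 of 32 members positive (adjusted p = 8.71e-06, but adjusted p = 0.0968 with an estimated correlation; without low libraries the latter was 0.0176). Of them 1 was called over the list alone, and 0 over all genes, with Mx2 going from 7.23 CPM to none (adjusted p = 0.104) and Igtp from 308 to 115 CPM (adjusted p = 0.186).

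Among other genes of the HPC-2 slope, Acp5 went from 222 CPM to none (adjusted p = 0.0382) and Blvrb from 298 to 62.4 CPM (-0.93, SE 0.21, adjusted p = 0.0389). Rises were called for Fanci (4.19 to 174 CPM, 2.03, SE 0.45) and Gpcpd1 (37.3 to 347 CPM, 1.15, SE 0.25), both at adjusted p = 0.0341, and for the annexin genes Anxa5 (0.88, SE 0.20, adjusted p = 0.0382) and Anxa2 (0.92, SE 0.22, adjusted p = 0.0432). With voom all of these slopes lost their calls (adjusted p = 0.133 for Psmb9 to 0.663 for Gpcpd1), Tgtp2 included (0.17), which alone kept its call in every omission. Acp5 was lost without 3 weeks replicate 2 (adjusted p = 0.617), Fanci and Gpcpd1 without 16 weeks replicate 1 (0.0904 and 0.0955), Anxa5 without 16 weeks replicate 2 (0.137). Anxa2 was lost without any of 3 libraries (up to 0.0597), Blvrb of 6 (up to 0.0615), Ube2l6 of 7 (up to 0.0877) and Psmb9 of 9 (up to 0.0735). In all, 7 genes rose and 70 fell, 11 of which were also called without near-identical and low libraries, and single omissions gave 77 to 489. Mitosis genes had 21 of 27 positive over the weeks (adjusted p = 4.39e-10, but adjusted p = 0.0798 with an estimated correlation), with 0 called either way and Prc1 going from 112 to 351 CPM (adjusted p = 0.217).

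The average effect of transplant differed between HSC and HPC-1 for 1 gene, Plac8. The difference was a log2 change of 2.39 (SE 0.47, adjusted p = 0.0409). In HSC it rose from 176 to 720 CPM, and in HPC-1 it was at 3343 CPM at steady state and 2498 CPM after transplant. The call was lost with RLE scaling (1.86, adjusted p = 0.153) and with voom (2.45, adjusted p = 0.287). Oxidative phosphorylation genes had 31 of 36 members positive for HSC over HPC-1 (adjusted p = 0.000546, but adjusted p = 0.684 with an estimated correlation). Cox5a (0.74, SE 0.26) and Cycs (0.96, SE 0.35) came first at adjusted p = 1, with 0 called either way. Ageing-associated genes had 6 of 24 positive (adjusted p = 0.00547, but adjusted p = 0.469 with an estimated correlation; without low libraries the latter was 0.00199, and without near-identical ones 0.051). The 4 members with the smallest p, Cd38, Ehd3, Ghr and Nupr1, had the opposite sign (adjusted p = 1 each), with 0 called either way.

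Between HSC and HPC-2 edgeR called 0 genes for the difference in effect, with 743 at an unadjusted p under 0.05, while DESeq2 called 1297 and voom 228. Without near-identical libraries 150 were called. DNA replication genes had 21 of 27 members positive (adjusted p = 0.00112, but adjusted p = 0.611 with an estimated correlation), with Tyms (0.88, SE 0.30, adjusted p = 0.509) first and 0 called either way. Ageing-associated genes had 9 of 24 positive (adjusted p = 0.0198, but adjusted p = 0.611 with an estimated correlation; without low libraries the latter was 2.82e-05, and without near-identical ones 0.64), with Jam2 (adjusted p = 0.253) and Nupr1 (-4.15, SE 1.23, adjusted p = 0.27) first and 2 called over the list alone.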

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

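The tests of the near-identical libraries, of libraries with few detected genes and of weeks without a count, and all tests without low or near-identical libraries, were chosen only after the results were seen. In the steady-state groups 114 combinations of group and measure were tested for 1 library lying apart, and 8 had one; chance alone gives about 1 in 20. Kit was at 570 CPM in HSC replicate 8 (nearest library 308 CPM), and Ly6a at 858 CPM in HSC replicate 7 (346 CPM). In HPC-1 the MHC class II score was 4.82 in replicate 3 (nearest 5.64), and the unfolded protein response score 5.10 in replicate 8 (5.86). In HPC-2 the DNA replication score was 3.54 in replicate 1 (6.23), the mature neutrophil score 5.94 in replicate 4 (1.24), the B cell score 2.25 in replicate 7 (0.78), and Ly6a 1710 CPM in replicate 1 (270 CPM).

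Between HSC and HPC-1 the effect of transplant differed for Plac8 (log2 change 2.39). Relative to other genes, HSC were more positive for the lists of oxidative phosphorylation (adjusted p = 0.000546), ribosomal proteins (4.79e-07) and B cell genes (0.000928). More negative were ageing-associated (0.00547), mature neutrophil (0.041), monocyte and macrophage (0.0029) and mast cell and basophil genes (0.0159). Against HPC-2, HSC were likewise more positive for DNA replication (0.00112), ribosome biogenesis (0.00112), oxidative phosphorylation (0.0204, mean log2 change 0.04) and B cell genes (0.00518). They were more negative for HSC identity (0.0384), mitosis (0.00795), cell cycle inhibition (0.045), ageing-associated (0.0198) and monocyte and macrophage genes (0.0114). With an estimated correlation none of these lists was called over all libraries. Without low libraries the ageing-associated list then was, against HPC-1 (0.00199) and HPC-2 (2.82e-05), as were B cell genes against HPC-1 (0.0394), but without near-identical libraries neither list was (0.051, 0.64 and 0.0912). At the preset correlation, mast cell and basophil genes against HPC-1 were lost without low (0.216) and without near-identical libraries (0.0564). Against HPC-2, mitosis (0.644 and 0.747) and cell cycle inhibition (0.209 and 0.065) were lost in both cases, HSC identity without low libraries (0.0639), and ageing-associated (0.052) and B cell genes (0.202) without near-identical ones. Without both kinds of library the mean log2 changes of mitosis (-0.33), cell cycle inhibition (-1.15) and HSC identity (-1.69) against HPC-2 stayed negative. Of their members 11 of 27, 8 of 14 and 7 of 25 were positive.

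Libraries were also split at random, the real split being counted among the splits. For the HSC average 1 of 50 splits gave as many genes (755, highest other 496). For the HPC-1 average it was 1 of 50 (190, highest other 2). False calls of the fit are not excluded by this, as the splits broke up the weeks. Simulated data gave 214 and 88 false calls in the real groups, and with transplanted libraries as 1 group 0 and 2 genes were called. For the HPC-2 average 10 of 50 splits gave as many (155, highest other 522), so chance cannot be excluded. In HSC the values were 30 of 30 at 3 weeks (0, highest other 12), 3 of 30 at 4 weeks (1 and 487), 3 of 30 at 5 weeks (2 and 6) and 1 of 30 at 6 weeks (3 and 1). At 8, 10, 13 and 16 weeks, with 0 genes called, all 30 of 30 did, with 0, 1, 2100 and 73 as the highest others. In HPC-1 it was 1 of 30 at 3 weeks (4 and 1) and 30 of 30 at 16 weeks (0 and 0), in HPC-2 30 of 30 at 3 weeks (0 and 1957) and 14 of 30 at 16 weeks (7 and 1661). As 1 of 30 is the smallest share possible and unadjusted, chance is excluded for no week.

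For the slopes 4 of 50 splits gave as many genes in HSC (31, highest other 36), so chance cannot be excluded for this count. It was 1 of 50 in HPC-1 (27 and 18) and 1 of 50 in HPC-2 (77 and 55). Between HSC and HPC-1 at steady state it was 1 of 50 (65 and 0). Between HSC and HPC-2 it was 3 of 50 (151 and 725), where chance cannot be excluded. The interactions, over genes of at least 10 CPM, gave 1 of 21 for HPC-1 (1 and 0), the smallest share that 21 splits allow. For HPC-2 it was 21 of 21 (0 and 4), fixed in advance as 0 genes were called. None of these shares was adjusted over the comparisons. Splits with far more genes than the real one (HPC-2 average and weeks, HSC against HPC-2, HSC at 4, 13 and 16 weeks) point to a structure of the samples, not traced further. For the gene lists on average, 1 of 100 splits gave as many tests (30, highest other 27). By population it was 16 of 100 in HSC, 1 of 100 in HPC-1 and 60 of 100 in HPC-2, so chance can be excluded only for the total and HPC-1. The median split called 13, so many single lists are called with random labels. Measured against the splits, the 6 lists described for HSC against HPC-1 at steady state held (adjusted p = 0.0433). No list of the averages (lowest 0.145), slopes (0.112), interactions (0.258) or HSC against HPC-2 (0.0867) did. At single weeks 4 to 80 of 100 splits called as many lists.

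The immediate early score swung between weeks, in HSC from 3.83 at 6 weeks to 7.08 at 8 weeks. Each of 8 blocks of 12 description numbers held the transplanted libraries of 1 week and up to 3 steady-state libraries. The score of the steady-state libraries followed that of the transplanted ones of the same block (Spearman rho 0.74, exact permutation test, adjusted p = 0.0458 over 5 relations), which is what handling on the day of harvest would give. The week means of HSC and HPC-1 had a Pearson r of 0.99, so the swing was largely shared by these populations. Their libraries of a week lie in the same block, so this cannot exclude a smaller response that differs between stem cells and progenitors. The labels do not say what the description numbers stand for, so it stays open what the libraries of a block shared.

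Of the 755 genes called in the HSC average 741 were lower, as were 209 of 214 false calls in simulated data. Among these 97.3% had at least 1 week without a count, against 69.4% of other genes of the same level, but the call itself could select such genes, and with the transplanted libraries as 1 group no gene was called in either direction, so it stays open whether weeks without a count are the cause. Libraries with few detected genes are argued against, since 533 of the 755 genes were still called without them; 822 were called lower there, where groups of 2 loosened the filter. Whether sparse genes seen in few libraries explain the pattern cannot be told apart from other causes, as the median lower gene had a count in 4 of 8 steady-state libraries, like other genes of the same level. With the transplanted libraries as 1 group and a block per 12 description numbers, 3 genes were called, among them Plac8 (log2 change 1.96, adjusted p = 0.023).

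In 6 pairs, libraries under different labels had near-identical counts. At most 1 gene per pair had 20 or more counts in one library and none in the other, against 102 or more genes in every other pair, as 1 cDNA sequenced under 2 labels would give. Cell populations that are that alike are argued against. None of the 149 pairs of replicates of a group had a chi-square per degree of freedom under 25.4. The 3 pairs of HPC-1 with HPC-2 had the HPC-1 profile, as given for Dntt above. For the other 3 pairs it stays open which label is right.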

How the results depend on the processing

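Tests without low or near-identical libraries, of genes of at least 10 CPM, and of transplanted libraries as 1 group (also with a block) were chosen only after the results were seen. Depth was 3551908 to 8492759 counts per library, and the genes called in the average effects had a median mean of 1.61, 1.29 and 4.32 CPM in the 3 populations. The tests of single weeks had 3 libraries on 1 side. Counts below are of called genes, with HSC, HPC-1 and HPC-2 in that order unless named, and weeks in ascending order. Where no cause is given, the cause was not tested.

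Across the gene lists described, all 56 tested were the same with RLE scaling, and 9 were the same and 51 weaker with an estimated correlation. For the 4 lists described in the interactions, RLE scaling, the missing filter and the replicate block were not run. With fry 29 were the same, 27 weaker and 4 reversed; with voom 58 were the same and 2 stronger. Among named genes, 243 results were the same with RLE scaling, 21 weaker and 3 stronger. DESeq2 gave 186 the same, 5 weaker and 72 stronger, and voom 188, 19 and 60. Without low libraries the values were 227, 22 and 18, without near-identical ones 228, 22 and 17. Among genes of at least 10 CPM 212 were the same and 37 weaker. In single omissions 6511 gene results were the same, 577 weaker and 80 stronger, and 1129 list results the same, 47 weaker, 2 stronger and 1 reversed.

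Of 87 list tests for the average effects, 30 were called in the chosen test, 0 with an estimated correlation and 13 with fry. Fry gave the opposite direction for 4 lists: HSC identity on average in HSC (adjusted p = 0.992), DNA replication (0.53) and ribosome biogenesis (0.628) on average in HPC-2, and immediate early genes at 3 weeks in HPC-2 (0.699).

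Replicate numbers paired the samples weakly at most. Libraries with the same number deviated together with a mean correlation of 0.00577, 0.0505 and 0.0109 in the 3 populations, with 7, 30 and 15 of 108 pairs over 0.1. Across populations at steady state it was 0.0967 (9 of 22), and 0.0408 (6 of 22) by the order of the description numbers. With the replicate number as a block HPC-2 at 16 weeks had 4 genes. The averages, HSC at 4, 5 and 6 weeks and HPC-1 at 3 weeks had 0. The HSC slope had 4 genes, HSC against HPC-1 and HPC-2 at steady state 102 and 1, and 10 lists were called. The block reversed 3 average HSC lists: DNA replication (0.205), HSC identity (0.649) and ageing-associated genes (0.944). A block by description number gave 2 genes for HSC against HPC-2.

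Without a low-count filter the averages had 2733, 2087 and 1324 genes and the slopes 1243, 1272 and 1447. HSC at 3, 5, 8 and 10 weeks had 3, 5, 3 and 1, HPC-1 at 16 weeks 3, and HPC-2 at 3 and 16 weeks 1 and 12. The interactions of HSC with HPC-1 and HPC-2 had 6 and 16, and the steady-state comparisons 32 and 10.

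RLE scaling gave 352 genes for the HPC-2 average, HSC at 3, 5 and 6 weeks 1, 0 and 0, and HPC-2 at 16 weeks 1. The interactions had 0 and 1. In HPC-1 at 3 weeks it called 2 higher and 1 lower, against 2 and 2.

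Voom called 327 genes for the HSC average and 4 for the HPC-2 average. HSC had 758, 496, 691, 103, 313, 84, 21 and 53 over the 8 weeks, HPC-1 at 3 and 16 weeks 588 and 6, and HPC-2 379 and 16. Slopes had 104, 128 and 3, interactions 190 and 228, and steady-state comparisons 1016 and 62.

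DESeq2 called 113 genes for the HPC-1 average and 1135 for the HPC-2 average. HSC had 710, 189, 620, 144, 640, 119, 273 and 937 over the 8 weeks, HPC-1 at 3 and 16 weeks 387 and 65, and HPC-2 302 and 1964. The HSC and HPC-2 slopes had 235 and 166, interactions 605 and 1297, and steady-state comparisons 146 and 344.

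With only the 2 compared groups in the fit, HSC at 4, 5 and 6 weeks had 0, 0 and 0 genes, HPC-1 at 3 weeks 9 and HPC-2 at 16 weeks 0. With weeks on a linear scale the HSC and HPC-2 slopes had 12 and 294.

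With transplanted libraries as 1 group the averages had 0, 2 and 0 genes. With a block per 12 description numbers added they had 3, 1 and 0. Among genes of at least 10 CPM the averages had 2, 3 and 7, the slopes 1, 3 and 0, HSC at 3 and 8 weeks 1 and 2, HPC-1 at 3 weeks 9, HPC-2 at 16 weeks 19, and HSC against HPC-2 29. Fewer genes were tested there.

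Without low libraries, which left 3 HPC-2 libraries at steady state and 1 at 16 weeks, the HPC-2 average had 8 genes, HSC at 3, 4, 5, 8 and 16 weeks 148, 6, 17, 11 and 6, and HPC-2 at 16 weeks 104. The HSC and HPC-2 slopes had 101 and 234, the interaction with HPC-1 4, and the steady-state comparisons 353 and 69. Adding the limit of 10 CPM gave averages of 31, 3 and 19, slopes of 0, 3 and 1, interactions of 10 and 3, and steady-state comparisons of 228 and 100. HSC at 3, 4, 5, 6, 8 and 16 weeks then had 233, 14, 32, 11, 25 and 8, HPC-1 at 3 weeks 9, and HPC-2 at 3 and 16 weeks 1 and 172.

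Without near-identical libraries the HPC-1 and HPC-2 averages had 122 and 0 genes, their slopes 43 and 50, HSC at 3, 4 and 8 weeks 95, 0 and 1, and HPC-2 at 3 weeks 1. The interaction with HPC-2 had 150, and the steady-state comparisons 119 and 1574. Without low libraries as well, the HPC-1 and HPC-2 averages had 122 and 9, the HSC and HPC-1 slopes 101 and 43, and HSC at 3, 4, 5, 8 and 16 weeks 148, 6, 17, 11 and 6. HPC-2 at 3 and 16 weeks had 11 and 208, the interactions 4 and 7, and the steady-state comparisons 447 and 390. That left 1 HPC-2 library at steady state and 1 at 16 weeks, each assumed to vary like the other groups. Slamf1 between HSC and HPC-2 reversed there, to a log2 change of -0.27. Of the genes called with all libraries, 533 of 755 were still called in the HSC average, 77 of 190 in HPC-1 and 1 of 155 in HPC-2. In the slopes it was 23 of 31, 17 of 27 and 11 of 77, and between HSC and HPC-2 at steady state 10 of 151.

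Leaving out single libraries gave 442 to 1312 genes for the HSC average, 93 to 432 for HPC-1 and 0 to 304 for HPC-2. In HSC the ranges were 0 to 95 at 3 weeks, 0 to 2 at 4, 0 to 6 at 5, 1 to 4 at 6, 0 to 6 at 8, 0 to 2 at 10 and 0 to 59 at 16 weeks. HPC-1 at 3 weeks had 0 to 7, and HPC-2 at 3 and 16 weeks 0 to 17 and 1 to 450. The slopes had 86 to 155, 50 to 86 and 77 to 489, and the steady-state comparisons 7 to 121 and 4 to 590. The HSC identity list in the HSC average ran from 5.88e-06 to 0.949, with its direction reversed without steady-state replicate 8.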

Other observations

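No test was added for this part, and its values were chosen only after the results were seen. The score of mast cell and basophil genes in HPC-1 was highest at 4 and 5 weeks after transplant. The mean log2(CPM + 1) was 2.42 at steady state (n = 8) and 3.58, 5.30, 4.52 and 3.05 at 3, 4, 5 and 6 weeks (n = 3 each). From 8 to 16 weeks it was 2.23, 3.19, 1.58 and 2.17. Tpsb2 was at a mean of 3.64 CPM in steady-state and 77.9 CPM in transplanted HPC-1, Cma1 at 11.1 and 128 CPM, and Mcpt4 at 0 and 21.8 CPM, with counts in 9 of 24 libraries. Cpa3 was at 354 and 419 CPM, with counts in every HPC-1 library.

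The interferon response score at 3 weeks and at steady state was 5.14 and 4.08 in HSC, 5.64 and 4.68 in HPC-1, and 5.66 and 3.38 in HPC-2. Pf4 stood in HSC at 444 CPM at steady state and 1440 CPM over the weeks after transplant, at 465 and 721 CPM in HPC-2, and at 19.5 and 19.0 CPM in HPC-1.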
